A study of Mus musculus with 6 samples.

How the data were processed

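Bulk RNA of sorted tumour cells from orthotopic mouse PDAC was sequenced in 3 KPC and 3 KPSC libraries, prepared with a TruSeq kit. Groups follow the sample titles. The submitters' processing notes name the mm10 build and CASAVA 1.7; the aligner, the read counter and the gene annotation are not given in the sources used here, nor is whether counting used strand, so reads of overlapping and antisense genes cannot be told apart.

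The deposited table holds, for 25450 rows, a signal per library that behaves as a gene read count divided by a size factor per library, with gene start, end and length in bases. It also holds the authors' group means and their p-values and adjusted p-values for KPSC against KPC, which are quoted only as the authors' deposited table. Size factors of 0.828 to 1.19 returned whole reads for 100.0% of values within 0.01 of a whole number. Of the rows, 7265 had a symbol and no value, and 18185 had values. All 399 rows whose symbol contains NA had no value, and 5 further rows, whose symbols had lost those letters (Nmnat1, Nanog, Nanos1, Nat2 and Tsnax by their gene IDs), were left out. Mitochondrial mRNAs and most replication histones were not analysed here for lack of values. Gene IDs were matched to GENCODE M21 (GRCm38), where 18175 matched and 10 did not; 17506 of 18170 genes shared their start and end with it, and all 18170 overlapped.

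The main test was limma 3.58.1 (eBayes with a mean-variance trend) in R 4.3.3 on log2(value + 1), over genes with a value of at least 1 in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had allowed for either unit before the data were examined: edgeR for counts, limma for normalised values. As the values are normalised, limma is the main test. edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads was added after the data were seen and called 2474 genes; DESeq2 1.42.0 and limma-voom on those reads were run as alternatives set beforehand. A pseudocount of 1 understates the changes of low genes. A gene with 0 reads in a group was given a bound against 3 reads per library, which covers counting error only.

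Gene lists, 45 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01, as 1 family of 43 lists with at least 3 tested genes. With an estimated correlation, 0 of the 20 lists past the threshold stayed past it. The rotation test fry, which asks whether a list's genes move on balance in a direction, called 4 lists, and its mixed form, for changes in either direction, called 33. Named genes were fixed by rule: Setd2 and the study genes, Xist and Ddx3y; the 10 highest and 10 lowest fold changes among called genes whose groups do not overlap, with at least 10 CPM in the higher group and an established symbol; and in each list up to 2 called genes of smallest adjusted p per direction, or the gene of smallest p where none was called. This gave 117 genes, of which some are not reported here. Chromosome medians covered genes with a mean value of at least 50.

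No pair of libraries matched within sampling noise (chi-square per degree of freedom of 38.7 or more). On simulated counts with the real means and library sizes, for KPSC against KPC and 16513 genes tested, limma recovered 63% of 100 genes changed 2-fold and 90% of 100 changed 4-fold, with 7 false among 160 calls. edgeR, over 14348 genes, recovered 66% and 91% with 11 false among 168. For both tests the changed genes were drawn from those with a mean value of at least 50, so recovery of lower genes was not measured. Unchanged data gave 2 genes and 1 of 43 lists, and a list shifted 2-fold was called with 1 other list. Each gene was drawn independently, so these list results do not show how often camera calls lists whose genes move together.

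The alternatives were other scalings, filters, pseudocounts and variance models, a replicate block, leaving out each library, count tests on recovered reads, other list tests and, added later, acinar and leukocyte covariates, libraries with at most 5% acinar reads, and a fit without acinar and islet genes. Tables were made with Python 3.11.15 and pandas 2.3.3 and figures with matplotlib 3.10.9.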

Results

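RNA was measured by bulk sequencing in 6 libraries of tumour cells sorted from orthotopic pancreatic ductal adenocarcinomas (PDAC), tumours grown in the pancreas of C57BL/6 mice. The libraries fell into 2 groups of 3, named KPC and KPSC after their titles; the labels do not spell these names out, nor which markers the sort used. Over the genes listed, the KPC libraries held 15753044, 17746969 and 14662710 reads and the KPSC libraries 16763856, 15215066 and 16995401. Values below are normalised read counts, given as mean ± SD with n = 3 per group, and fold changes are KPSC against KPC on the log2(value + 1) scale. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

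The comparison of KPSC with KPC bears on Setd2, the histone H3 lysine 36 methyltransferase named in the genotype field. That field gives a Setd2 knockout for the libraries titled KPC and the wild type for those titled KPSC, whereas an added letter in a title usually marks the added allele, so groups are named by title and no direction is drawn from the genotype. Setd2 (chromosome 9, 110532597 to 110618633, GRCm38) stood at 1338, 1099 and 1046 normalised reads in KPC replicates 1, 2 and 3 and at 859, 908 and 1042 in KPSC replicates 1, 2 and 3. The means were 1161 ± 156 and 936 ± 94.6, a log2 fold change of -0.31 (SE 0.12) that did not pass the test (limma, adjusted p = 0.148). Reads counted over a whole gene need not fall when only some exons are deleted, so these values do not settle which group lacks functional Setd2.

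Of 4 genes that publications on Setd2 in PDAC discuss, Cxcl1 fell and Bmp2 rose. Because these genes may have been picked on these libraries, they are not independent evidence. Cxcl1, a chemokine that attracts neutrophils, went from 782 ± 347 to 299 ± 58.8 (log2 fold change -1.30, SE 0.30, limma adjusted p = 0.0269), and its call was lost without KPC replicate 3 (adjusted p = 0.0814) and without KPSC replicate 2 (adjusted p = 0.09). It lies on chromosome 5, where the median log2 fold change of 784 expressed genes was -0.24. Bmp2, a secreted growth factor, went from 125 ± 15.7 to 345 ± 86.8 (log2 fold change 1.43, SE 0.22, limma adjusted p = 0.00538). Its call was lost in the 3 libraries with at most 5% of reads from acinar enzyme genes (0.91, adjusted p = 0.0587). With the leukocyte level as a covariate neither gene passed (Bmp2 0.77, adjusted p = 0.495; Cxcl1 -0.50, adjusted p = 0.791). Cxadr, the coxsackievirus and adenovirus receptor of tight junctions, had a log2 fold change of -0.26 (limma adjusted p = 0.141). Csf2 had 0.57 (limma adjusted p = 0.462) at means of 40.5 and 57.3 reads, and 0.24 to 0.99 on leaving out each library. Exact two-sided permutation tests gave p = 0.2 for Csf2 and 0.1 for each of the other genes including Setd2, 0.1 being the smallest p that 3 against 3 allow.

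**Figure D1:**
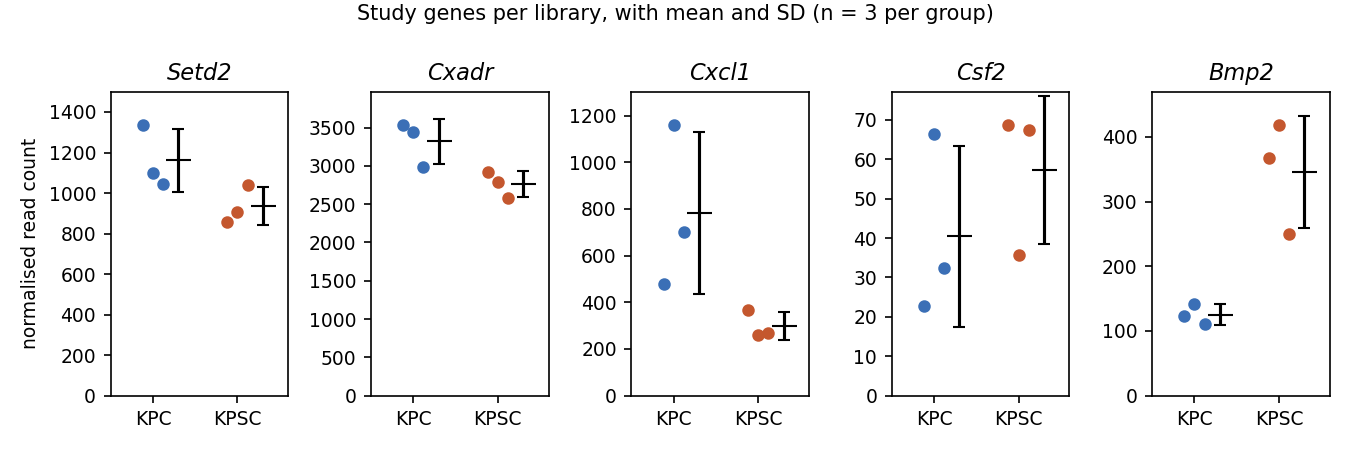
Normalised read counts (vertical axis) of Setd2, Cxadr, Cxcl1, Csf2 and Bmp2 in the 3 KPC (blue) and 3 KPSC (orange) libraries, one point per library, with the group mean and SD beside them in black. Bmp2 lies higher and Cxcl1 lower in every KPSC library than in every KPC library, and the Csf2 values of the groups overlap.

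The libraries titled KPSC held far more mRNA of Trpa1, Krt14 and the mucins Muc3 and Muc5b, and far less of 4 Y-linked genes and of the protocadherins Pcdh10 and Pcdh11x. Among the highest were Trpa1, an ion channel with 0 reads in all KPC libraries and 174 ± 30.3 normalised reads in KPSC (at least 61.4-fold higher, against 3 reads per library), and the homeobox gene Pitx1 (log2 fold change 6.75). Krt14, a keratin of basal epithelia, rose by 6.08 on the log2 scale, and the mucins Muc3 and Muc5b by 5.75 and 4.77. Agr2, a chaperone of mucin folding, rose by 5.10, and Fcgbp, a protein of mucus, by 4.87. Nptx1 (5.74), Megf10 (4.87) and the intestinal homeobox gene Isx (4.34) completed the 10 highest under the naming rule. For highest and lowest alike, that rule ranks only called genes with at least 10 CPM in the higher group, groups that do not overlap and an established symbol. The 10 lowest were Csmd3 (-4.62), the Y-linked genes Eif2s3y (-4.56), Ddx3y (-4.51), Kdm5d (-4.37) and Uty (-3.91), the protocadherins Pcdh11x (-4.06) and Pcdh10 (-3.81), Akr1c14 (-3.87), Adamdec1 (-3.80) and Paqr6 (-3.76). Ddx3y fell from 537 ± 108 to 22.4 ± 3.87, while Xist, the RNA of the inactive X chromosome, stood at 3958 ± 722 and 3306 ± 169 (log2 fold change -0.24, adjusted p = 0.3).

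Over all 16737 genes tested, 2406 passed the threshold, 1274 higher and 1132 lower in KPSC, and 934 of these also changed by more than 2-fold (468 of them higher). The groups did not overlap for 5818 genes (34.8%, where chance gives 10%). The authors' deposited table called 2946 genes (1556 higher, 1390 lower); 2332 genes were called in both, all in the same direction. The count fell to 1403, 1314 and 1250 without KPC replicates 1, 2 and 3 and to 1299 and 1290 without KPSC replicates 1 and 2. KPSC replicate 3 stood apart, with a Pearson correlation of 0.947 and 0.954 with KPSC replicates 1 and 2, which correlated at 0.984 with each other, and the count was 3051 without it. Scaling to library size only gave 385 higher and 870 lower (30.7% higher, against 53%).

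**Figure D2:**
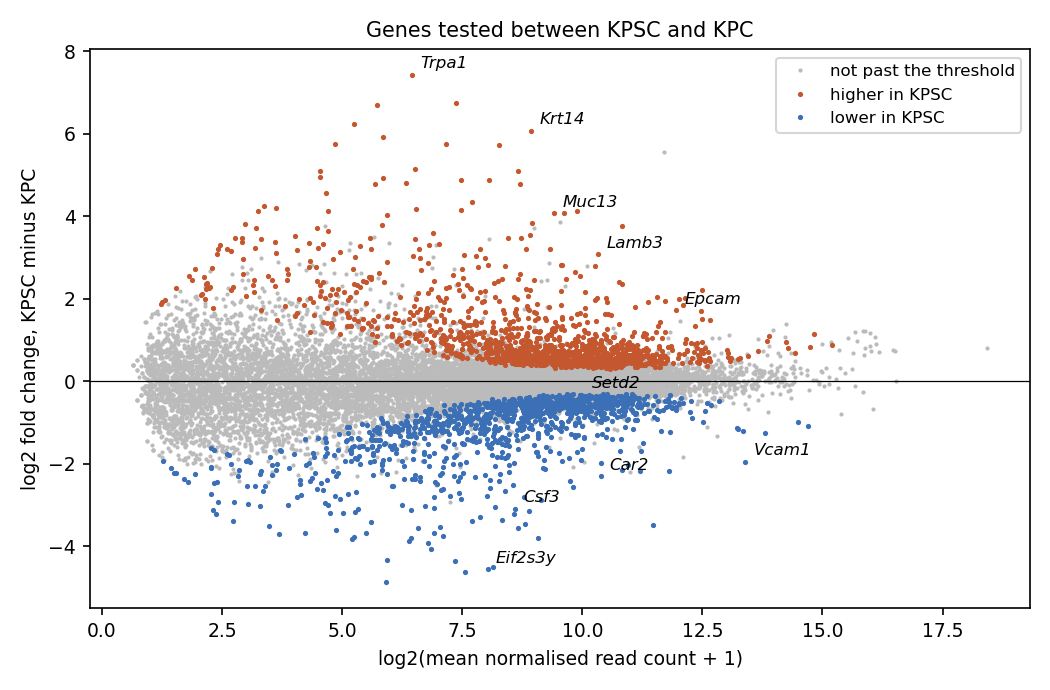
Log2 fold change of KPSC against KPC (vertical axis) against log2 of the mean normalised read count plus 1 (horizontal axis), one point per gene tested, orange where higher and blue where lower in KPSC past the threshold and grey otherwise. The 1274 higher and 1132 lower genes include Trpa1 and Krt14 at the top and Eif2s3y at the bottom, and Setd2 lies among the grey points.

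Of 25 adhesion, junction and keratin genes, 12 rose and none fell over all genes tested (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.54. Epcam, an epithelial adhesion molecule, went from 1844 ± 355 to 6075 ± 1244 and the junction protein Jup from 3953 ± 178 to 7633 ± 806. The set test camera called the list higher (adjusted p = 8.99e-05, but adjusted p = 0.789 with an estimated correlation). The mean level of the list was 10.19 and 10.13 in KPSC replicates 1 and 2 and 9.11 in KPSC replicate 3, beside 9.25, 9.06 and 9.43 in KPC. As a share of reads, however, the list was higher in every KPSC library. It held 0.746%, 0.838% and 0.926% in KPSC replicates 1, 2 and 3, beside 0.505%, 0.589% and 0.499% in KPC. The median was 0.30 without KPSC replicate 1 and 1.02 without KPSC replicate 3. Without KPSC replicate 2, 7 genes of the list were higher, and without KPSC replicate 3, 17 were higher and 1 lower. In the 3 libraries with at most 5% of reads from acinar enzyme genes (KPC replicates 1 and 2 and KPSC replicate 3, the last assumed to vary like the others), 5 of these genes were higher and 3 lower, with a median of 0.21.

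Of 18 genes of the classical PDAC subtype, 9 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 3.93e-05, adjusted p = 0.362 with an estimated correlation). The lower count was 0 without KPC replicate 1 and 1 without KPC replicate 2 or 3 or KPSC replicate 1. Muc13, a membrane mucin, rose from 75.0 ± 21.1 to 1280 ± 316, and Ctse, a gastric protease, from 290 ± 62.9 to 1703 ± 376. Gata6, a transcription factor of that subtype, fell (log2 fold change -0.87, adjusted p = 0.0343). Of 14 basal-like genes, 4 rose, Krt14 and the protease inhibitor Cst6 (4.78) among them, and the cornified envelope gene Sprr1a fell (-1.54). That count was 5 and 1 adjusted over the list alone. The basal-like list was called higher (camera adjusted p = 0.0428, adjusted p = 0.747 with an estimated correlation), a call lost on leaving out any library other than KPC replicate 2 (adjusted p = 0.0591 to 0.118).

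The laminin gene Lamb3 rose strongly. It went from 269 ± 25.5 to 2292 ± 305, among 6 of 20 matrix genes that rose, with none lower, also adjusted over the list alone. The median of the matrix list was 0.08, and 0.12, 0.18, -0.03, 0.29, 0.16 and -0.10 on leaving out KPC replicates 1, 2 and 3 and KPSC replicates 1, 2 and 3 in turn, so its sign is unsettled. Its mean was 0.48 (camera adjusted p = 0.0387, adjusted p = 0.789 with an estimated correlation), and the call was lost without KPC replicate 1 (adjusted p = 0.0539), KPC replicate 3 (0.152) or KPSC replicate 3 (0.427). Lamb3, Ctse, Trpa1 and Epha4 lie on chromosome 1, where 723 expressed genes had a median log2 fold change of 0.39. Of 13 duct genes, 4 fell and none rose (2 higher and 5 lower adjusted over the list alone), but 2 rose without KPC replicate 3 and 1 without KPSC replicate 3. The carbonic anhydrase Car2 fell by 2.31 and Bicc1, an RNA-binding protein, fell by 1.69 on the log2 scale. The duct list was called lower (camera adjusted p = 0.0153, adjusted p = 0.789 with an estimated correlation), which was lost without KPC replicate 1 (adjusted p = 0.0591) or KPSC replicate 3 (0.051). Of 20 mesenchymal genes, 3 rose and none fell (4 and 1 adjusted over the list alone), among them Twist1 (2.04) and Cald1 (0.74), and the list did not pass (camera adjusted p = 0.0901). In that list 1 rose without KPSC replicate 2, and 2 rose and 2 fell without KPSC replicate 3.

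Lists of RAS-ERK output, cell division, respiration and cholesterol synthesis were called higher in KPSC by camera, each with adjusted p = 0.789 with an estimated correlation. Of 21 RAS-ERK output genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0153). The ephrin receptor Epha4 rose by 2.69 and Emp1 by 1.09, while the growth factors Ereg and Hbegf fell by 2.22 and 0.51. The call was lost without KPC replicate 3 (adjusted p = 0.118). Of 24 S phase genes, 4 rose and none fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0025), among them Cdc45 (0.54) and Rrm2 (0.67). Of 24 G2 and M phase genes, 2 rose, Cenpf (0.69) and Aurkb (0.52), with 2 adjusted over the list alone (camera adjusted p = 0.00195). Both cell cycle calls were lost without KPSC replicate 3 (adjusted p = 0.0587 and 0.0588). Of 23 respiratory chain subunits, 4 rose (6 adjusted over the list alone; camera adjusted p = 0.0025), Ndufs1 (0.60) of complex I, on chromosome 1, among them, and the call was lost without KPC replicate 1 (adjusted p = 0.0523). Of 19 cholesterol genes, Fdft1 (0.76) and Nsdhl (0.52) rose and 1 gene fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0112). That call was lost without KPC replicate 3 (adjusted p = 0.125) or KPSC replicate 3 (0.0709). The counts of higher genes, on leaving out KPC replicates 1, 2 and 3 and KPSC replicates 1, 2 and 3 in turn, were 2, 3, 2, 3, 7 and 4 in S phase, and 1, 0, 0, 0, 5 and 2 in G2 and M phase. In the same order they were 1, 3, 1, 1, 2 and 5 in the respiratory chain and 0, 3, 0, 0, 1 and 1 in cholesterol synthesis. The lower RAS-ERK genes numbered 0, 0, 2, 0, 1 and 2, and 1 S phase gene was lower without KPSC replicate 3.

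Lists of neutrophil cytokines, NF-kB targets, interferon-stimulated genes and hypoxia genes were called lower in KPSC by camera, each lost with fry (adjusted p = 0.264, 0.107, 0.185 and 0.228). Leukocyte markers lay lower with them, with list medians of -0.45 (pan-leukocyte), -1.15 (lymphocyte) and -0.65 (neutrophil), the last -1.20 without KPC replicate 1 and -0.33 without KPC replicate 2. Of 12 cytokines that attract or expand neutrophils, 3 fell and none rose (6 and 0 adjusted over the list alone). Csf3, the granulocyte growth factor, fell from 697 ± 350 to 75.5 ± 15.1 (log2 fold change -3.09, adjusted p = 0.00142). The list was called lower (camera adjusted p = 0.0107, adjusted p = 0.789 with an estimated correlation), a call lost without KPC replicate 2 (adjusted p = 0.0941). Of 17 NF-kB targets, 4 fell and none rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.789 with an estimated correlation). The adhesion molecule Vcam1, on chromosome 3, fell from 17050 ± 860 to 4425 ± 422 and the inhibitor Nfkbia from 1774 ± 207 to 1278 ± 112. Of 26 interferon-stimulated genes, 6 fell and none rose (10 and 0 adjusted over the list alone), Ifi44 (-1.39) and Ifit3 (-1.42) among them (camera adjusted p = 2.57e-05, adjusted p = 0.789 with an estimated correlation). In the 3 libraries with at most 5% acinar reads 3 were higher and 6 lower. Of 22 hypoxia and glycolysis genes, 5 fell and none rose (7 and 0 adjusted over the list alone), with Ankrd37 (-1.45) and the vasodilator peptide Adm (-1.93) among them (camera adjusted p = 0.00195, adjusted p = 0.789 with an estimated correlation). The counts of lower genes were 2, 2, 2, 3, 1 and 4 for the cytokines, on leaving out KPC replicates 1, 2 and 3 and KPSC replicates 1, 2 and 3 in turn, and 3, 2, 1, 1, 1 and 6 for NF-kB targets. They were likewise 5, 3, 4, 3, 2 and 17 for interferon-stimulated genes and 4, 5, 3, 3, 3 and 6 for hypoxia genes.

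Camera called 5 lists of leukocyte markers lower in KPSC, of which fry called the lymphocyte list alone (adjusted p = 0.0412), and most of the markers did not pass. The pan-leukocyte phosphatase Ptprc went from 2542 ± 220 to 1366 ± 399 and Coro1a from 3285 ± 497 to 1969 ± 174, among 3 of 8 pan-leukocyte markers that fell (7 adjusted over the list alone; camera adjusted p = 0.00049, adjusted p = 0.789 with an estimated correlation). T, NK and B cell markers fell in 7 of 15 cases (10 adjusted over the list alone), such as Gzma (-1.71) and Cd3g (-1.03), with a list median of -1.15 (camera adjusted p = 1.89e-05, adjusted p = 0.638 with an estimated correlation). Dendritic and MHC class II markers fell in 4 of 12 cases (6 adjusted over the list alone), H2-Ab1 (-1.21) and H2-Eb1 (-1.17) among them (camera adjusted p = 0.00264, adjusted p = 0.789 with an estimated correlation). Of 16 macrophage markers 2 fell, Csf1r (-0.50) and Cd14 (-0.69), with 1 adjusted over the list alone (camera adjusted p = 0.0025, adjusted p = 0.789 with an estimated correlation). Of 13 neutrophil markers 3 fell, also adjusted over the list alone, among them Cxcr2 (-1.34) and Csf3r (-1.12), and the list call (camera adjusted p = 0.0408, adjusted p = 0.789 with an estimated correlation) was lost without KPC replicate 2 (adjusted p = 0.223), KPC replicate 3 (0.051), KPSC replicate 2 (0.0751) or KPSC replicate 3 (0.0504). Counts of lower markers, on leaving out KPC replicates 1, 2 and 3 and KPSC replicates 1, 2 and 3 in turn, were 2, 2, 1, 1, 0 and 6 for pan-leukocyte and 2, 2, 1, 4, 2 and 10 for lymphocyte markers. Likewise they were 2, 3, 0, 2, 0 and 5 for dendritic, 3, 1, 0, 0, 1 and 2 for macrophage and 3, 2, 2, 3, 2 and 4 for neutrophil markers. Without KPC replicate 2, 1 neutrophil marker was higher. The sex-linked list, with 4 of 5 genes lower, also adjusted over the list alone, was called lower (camera adjusted p = 1.86e-06, adjusted p = 0.362 with an estimated correlation).

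RNA of normal pancreas differed widely between libraries within each group. Acinar enzyme genes held 2.46%, 0.941% and 7.22% of reads in KPC replicates 1, 2 and 3 and 18.3%, 9.43% and 0.39% in KPSC replicates 1, 2 and 3. None of the 21 acinar genes passed the test, also adjusted over the list alone; Amy2a5, an amylase, stood at 1587 ± 1368 and 6745 ± 6322, and the list was not called (camera adjusted p = 0.343). That count turns on 1 library. Without KPSC replicate 3, 15 acinar genes were higher (camera adjusted p = 2.6e-08). None of the 10 islet genes passed either, also adjusted over the list alone. Chgb had a log2 fold change of -2.93 (limma adjusted p = 0.322), and of -4.71 to -0.62 on leaving out each library. The islet list was not called (camera adjusted p = 0.133, but 0.00149 without KPSC replicate 1). Its mean level was 3.15 in KPSC replicate 3 beside 7.02 or more in the other libraries. With acinar levels as a covariate, 2402 of the 2406 genes still passed the threshold. Those levels correlated at only 0.21 with the group, so they could change group differences little. Fibroblast markers had a median of 0.07 (0 to 0.22 on leaving out each library) with Lum lower (-0.61), none adjusted over the list alone, and none of the 10 endothelial markers passed, also adjusted over the list alone (Cldn5 -0.27; camera adjusted p = 0.904 and 0.717). Of 9 red cell and platelet markers, Hbb-bs (1.13) and Hba-a1 (1.16) rose and Itga2b (-0.68) fell, also adjusted over the list alone (camera adjusted p = 0.388); Hba-a1 has a near-identical copy, so its count is uncertain. Of 10 mesothelial, adipocyte and Schwann cell markers, S100b (2.88) and Msln (0.80) rose and Cidec (-1.42) and Wt1 (-1.16) fell, also adjusted over the list alone (camera adjusted p = 0.66). Lower fibroblast markers numbered 0, 0, 0, 0, 0 and 3 and higher red cell markers 0, 0, 1, 2, 0 and 2 on leaving out KPC replicates 1, 2 and 3 and KPSC replicates 1, 2 and 3 in turn (limma). Lower red cell markers numbered 0, 0, 0, 0, 0 and 1 and lower genes of the last list 0, 0, 0, 0, 1 and 1.

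**Figure D3:**
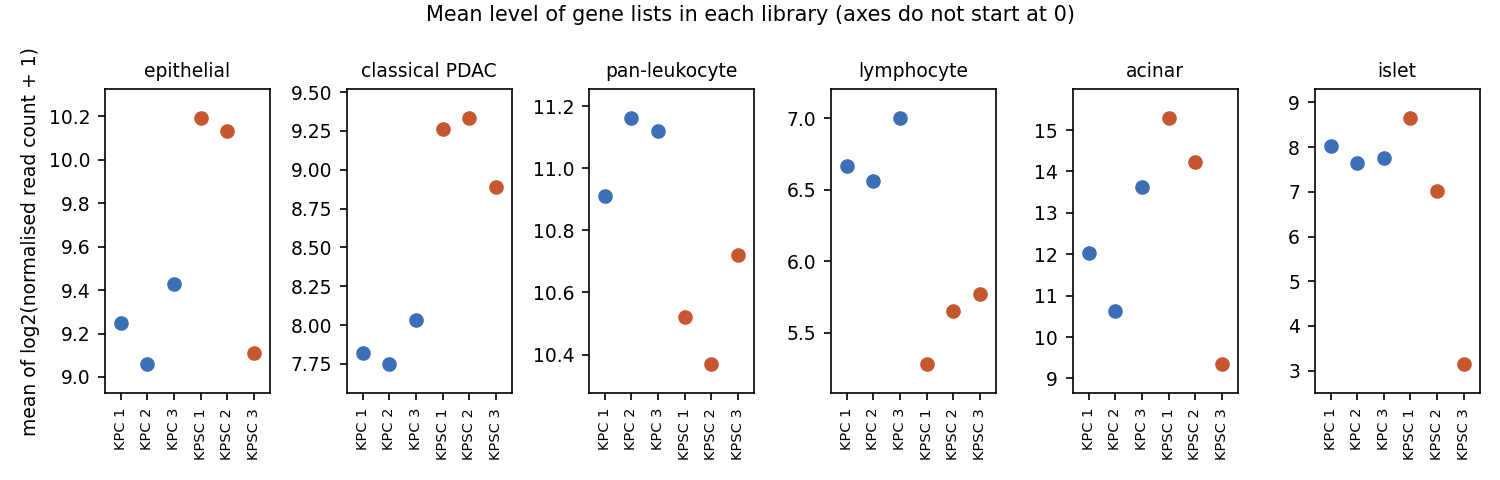
Mean of log2(normalised read count + 1) over the genes of 6 lists (vertical axes, which do not start at 0), one point per library, KPC in blue and KPSC in orange. Epithelial levels of KPSC replicate 3 (9.11) lie near those of KPC, its islet level (3.15) lies below all others, and lymphocyte and pan-leukocyte levels of the 3 KPSC libraries lie below the 3 KPC libraries.

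Other lists were not called by camera. The chromatin list, drawn up beforehand for H3 lysine 36 methylation, moved both ways. Setd3 (0.38) and Phf19 (0.86) rose and Kdm4b (-0.42) and Dnmt3a (-0.52) fell among 19 genes (3 and 2 adjusted over the list alone, camera adjusted p = 0.365). Membership of that list does not show that a gene acts on this mark. In DNA repair, Bard1 (0.66) rose and Rbbp8 (-0.64) and Pms2 (-0.60) fell among 22 genes (3 and 4 adjusted over the list alone; camera adjusted p = 0.596). Among p53 targets, Perp (1.53) and Phlda3 (0.95) rose and Pmaip1 (-0.52) fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.527). In the TGF-beta and BMP list, the BMP inhibitor Grem1 rose by 3.55 beside Bmp2 and Fst, and Id2 fell by 0.38 (3 and 1 adjusted over the list alone). Wnt targets were divided, with Apcdd1 (1.21) and Rnf43 (0.99) among 3 higher and Znrf3 (-0.63) and Axin2 (-0.41) lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.536). Nuak2 (0.65) rose and Arhgef17 (-0.97) fell among YAP targets (1 and 1 adjusted over the list alone). Among immediate early genes 4 rose, Klf4 (1.03) and Klf2 (0.72) included (4 and 2 adjusted over the list alone). On leaving out KPC replicates 1, 2 and 3 and KPSC replicates 1, 2 and 3 in turn, limma called 0, 0, 0, 0, 1 and 2 chromatin genes higher and 0, 0, 1, 0, 0 and 3 lower, and 0 repair genes higher each time with 1, 1, 1, 1, 1 and 2 lower. The lower counts were 1, 0, 0, 0, 0 and 1 for p53 targets and for the TGF-beta and BMP list. For the others they were 0, 1, 0, 0, 0 and 1 for Wnt targets and 1, 1, 1, 1, 1 and 3 for YAP targets. Immediate early genes were higher in 2, 3, 2, 4, 2 and 3 cases and lower in 0, 0, 0, 0, 1 and 4.

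The amino acid genes Psat1 (0.52) and Asns (0.93) were among 4 genes that rose in the stress response list (6 and 1 adjusted over the list alone; camera adjusted p = 0.103). In the 3 libraries with at most 5% acinar reads none of that list was higher and 2 were lower; acinar genes, too, lay higher without KPSC replicate 3 (15 of 21). Srxn1 (0.53) and G6pdx (0.55) rose and Gclm (-0.80) fell among NRF2 targets (4 and 1 adjusted over the list alone; camera adjusted p = 0.293). In fatty acid metabolism, Cpt1a (0.39) rose and Elovl5 (-0.55) fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.365). Vtcn1, a ligand that restrains T cells, fell by 3.46 and Nt5e by 0.84 on the log2 scale (2 lower adjusted over the list alone; camera adjusted p = 0.64), and Pik3cd (-0.90) fell alone among 21 PI3K-AKT genes (1 adjusted over the list alone; camera adjusted p = 0.543). Ccl5 (-0.92) and Cxcl16 (-0.51) fell among other chemokines (2 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.218). No gene passed, also adjusted over the list alone, among MHC class I genes (Psmb8 -0.55, adjusted p = 0.0763; camera adjusted p = 0.149; without KPSC replicate 3, 6 of 13 lower and 0.00252), INK4 and other cell cycle inhibitors (Cdkn2c -0.23, adjusted p = 0.199; camera adjusted p = 0.701) and ribosomal proteins (Rpl7 0.60, adjusted p = 0.0766; camera adjusted p = 0.356). Median, mean and camera direction differed in sign for the immediate early (-0.08, 0, higher), TGF-beta and BMP (-0.03, 0.39, higher), YAP (0.01, -0.13, lower), fibroblast (0.07, 0.01, lower), endothelial (0.01, -0.04, lower) and cell cycle inhibitor lists (-0.01, 0.12, higher). Leaving out each library, these medians ran from -0.13 to 0.07, -0.05 to 0.07, -0.12 to 0.04, 0 to 0.22, -0.21 to 0.10 and -0.01 to 0.06. Their camera adjusted p were 0.867, 0.66, 0.647, 0.904, 0.717 and 0.701. Higher genes numbered 1, 0, 2, 1, 1 and 6 in the stress response, 1, 2, 1, 1, 2 and 2 among NRF2 targets and 1, 0, 0, 0, 0 and 1 in fatty acid metabolism, on leaving out KPC replicates 1, 2 and 3 and KPSC replicates 1, 2 and 3 in turn (limma). Lower genes numbered 1, 1, 1, 0, 0 and 3 in fatty acid metabolism, 0, 1, 0, 1, 0 and 2 among PI3K-AKT genes and 2, 1, 1, 1, 1 and 6 among other chemokines, of which 1 was higher without KPC replicate 2. Without KPSC replicate 3, 3 checkpoint ligands were lower and 1 higher, 1 cell cycle inhibitor was higher and 1 stress response gene was lower. There the stress response, other chemokine and ribosomal lists passed camera (adjusted p = 0.00727, 0.013 and 0.00485).

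Several of the named genes lie on chromosomes with a shifted median over expressed genes. Vcam1, Ifi44, Sprr1a, Car2, Pcdh10, Paqr6, Gclm and Vtcn1 lie on chromosome 3, with a median log2 fold change of -0.24 over 616 genes. Ereg, Muc3 and Pms2 lie on chromosome 5 with Cxcl1. Megf10, Hbegf, Gata6, Rbbp8, Pmaip1, Apcdd1, Csf1r and Cd14 lie on chromosome 18, with a median of -0.36 over 307 genes, and Bard1, Cenpf, Phlda3, Nuak2, Ptprc, Cxcr2 and Rpl7 lie on chromosome 1. H1f0, the only gene of the replication histone list with values, had a log2 fold change of 0.23 (adjusted p = 0.367).

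Some further called members of the lists are given here, chosen after their values were seen. Csf1 (-0.58) fell among neutrophil cytokines, Icam1 (-0.74) and Saa3 (-1.16) among NF-kB targets, and Pfkl (-0.64), Bnip3 (-1.28) and Ndrg1 (-0.99) among hypoxia genes. Slc4a4 (-0.90) and Prom1 (-1.21) fell among duct genes, Rac2 (-0.64) among pan-leukocyte, Mmp9 (-1.49) among neutrophil and H2-Aa (-1.14) and Cd74 (-1.09) among dendritic markers. Krt6a (3.38) and Lemd1 rose in the basal-like list, Phlda1 (0.71) and Epha2 (0.83) in RAS-ERK output, Vim (0.88) in the mesenchymal list, Fst (1.68) in the TGF-beta and BMP list and Notum (1.57) among Wnt targets. Mcm3 (0.65) and Mcm4 (0.62) rose in S phase, Sdhc (0.57) and Uqcrc2 (0.40) in the respiratory chain, Hspa5 (0.68) and Sdf2l1 (0.58) in the stress response, and Fos (1.21) and Klf6 (0.45) among immediate early genes.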

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

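The edgeR test on recovered reads, that test without acinar and islet genes, the acinar and leukocyte covariates and the fit to the 3 libraries with at most 5% acinar reads were chosen after the data were seen, the last with its limit moved from 10% to 5% once the acinar shares were known and with 1 KPSC library assumed to vary like the others. All 106 called named genes kept their direction under every alternative that gave them a value, and 18 also stayed past the threshold under each. Of these calls, 43 were lost on leaving out at least 1 library. Setd2 stayed short of the threshold throughout, with log2 fold changes of -0.48 to -0.20. The count of 2406 genes ranged from 103 to 3552: it was 1543 (825 higher, 718 lower) without a mean-variance trend, 1255 (385 higher) scaled to library size only, where the median of all genes moved to -0.168, and 3070 with DESeq2. Leaving out each library gave 1250 to 3051 genes, 698 to 1494 higher and 525 to 1557 lower. The leukocyte covariate, which has a correlation of -0.9 with the group, left 103 (60 higher, 43 lower), all 103 over 2-fold, and 13 lists. Some fold changes weakened there, as given for Cxcl1 and Bmp2 below, while the medians of the shifted chromosomes stayed near their size (0.371 and 0.376 on chromosome 1); why calls were lost was not tested. A test against a 1.5-fold minimum left 335 genes in place of 934. Deviations of same-numbered libraries from their group means correlated at -0.04, -0.18 and -0.28. In these deviations no library correlated best with its own number in the other group. Pairing by number was thus not seen, though these few values cannot exclude it. The replicate block gave 1014 genes (567 higher, 447 lower). The main test recovered 63% of simulated 2-fold changes in genes with a mean value of at least 50, so smaller changes were often missed. Apart from fewer libraries or the covariate's own construction, the cause was not tested. Every alternative set beforehand that applied to these values was run; limma on the normalised values was the main test.

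Cxcl1 was short of the threshold without a mean-variance trend (-1.30, adjusted p = 0.0783), under the block (-1.30, 0.0702), under the leukocyte covariate (-0.50, 0.791) and without KPC replicate 3 (-1.33, 0.0814) or KPSC replicate 2 (-1.22, 0.09); leaving out each library gave -1.61 to -0.97, and its adjusted p ranged from 3.68e-05 to 0.791. Bmp2 was short of it under the leukocyte covariate (0.77, 0.495) and in libraries low in acinar reads (0.91, 0.0587), with adjusted p from 1.36e-07 to 0.495. Amy2a5, not called, had the opposite sign under the leukocyte covariate (-4.28) and in libraries low in acinar reads (-1.21), as had Cdkn2c (0.07) under the former and H1f0 (-0.01) in the latter.

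The values that follow are adjusted p of the list tests. With an estimated correlation, 0 lists passed: p was 0.362 for the classical and sex-linked, 0.638 for the lymphocyte, 0.747 for the basal-like and 0.789 for the other 16 lists called. With fry, 4 lists passed, and the neutrophil cytokine (0.264), NF-kB, epithelial, pan-leukocyte and macrophage (0.107), interferon and matrix (0.185), RAS-ERK (0.14), duct (0.0899), S phase (0.227), G2 and M phase (0.307), hypoxia and respiratory chain (0.228), cholesterol (0.362), neutrophil (0.414) and dendritic lists (0.116) did not. Calls were lost for the matrix (0.0972) and neutrophil lists (0.0539) under quantile normalisation, for the neutrophil list (0.0658) without a trend, and for the basal-like list with a minimum value of 5 (0.0777) or a pseudocount of 0.1 (0.0543). The cholesterol call was lost on recovered reads with edgeR's TMM (0.0879), DESeq2 size factors (0.0924), upper quartile (0.0834), no filter (0.0511), a CPM of at least 5 (0.123), library size only (0.138), without acinar and islet genes (0.0811) and with DESeq2 (0.0989). Library size only also ended the RAS-ERK (0.0645), S phase (0.0745) and respiratory chain calls (0.0996) and called the acinar list higher (0.00205). The basal-like call was lost with the CPM filter (0.216) and with voom (0.302), which also ended the matrix call (0.0553). The mesenchymal list was called higher with DESeq2 (0.0181), the acinar covariate (0.0171), the leukocyte covariate (0.00676) and low acinar reads (0.0106), and the stress response list with DESeq2 (0.0378). The islet list was called lower under the block (0.0372), the acinar covariate (0.000256), the leukocyte covariate (2.92e-05) and low acinar reads (2.34e-17).

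In libraries low in acinar reads, calls were lost for the NF-kB, pan-leukocyte and neutrophil (0.079), interferon (0.286), RAS-ERK (0.527), epithelial (0.278), basal-like (0.204), respiratory chain (0.258) and dendritic lists (0.343), and the red cell list was called higher (0.0447). The acinar list turned to lower there (1.66e-14), which says nothing of the groups, since these libraries were chosen by their acinar reads and the lone KPSC library held the fewest. Uncalled lists of opposite sign were other chemokine and stress response (0.642), MHC class I (0.309), DNA repair (0.514), p53 (0.954), fatty acid (0.655), ribosomal (0.277), fibroblast (0.079) and endothelial (0.258). The leukocyte covariate ended the calls of NF-kB and pan-leukocyte (0.991), RAS-ERK (0.34), epithelial (0.577), basal-like (0.119), hypoxia (0.204), macrophage (0.134) and dendritic lists (0.802). It turned the sign of the acinar (3.2e-05) and endothelial lists (0.00409), both then called, and of neutrophil cytokine (0.632), other chemokine (0.204), interferon and checkpoint ligand (0.719), MHC class I and neutrophil (0.34), DNA repair (0.348), TGF-beta and BMP and stress response (0.802), Wnt (0.945), YAP (0.991), fatty acid (0.72), ribosomal (0.915) and fibroblast lists (0.0574). Uncalled lists also turned sign under quantile normalisation (ribosomal, 0.755), the block (immediate early and fibroblast, 0.991), library size only (fibroblast, 0.964), the CPM filter (cell cycle inhibitor, 1) and the acinar covariate (acinar 0.95, fibroblast 0.7, endothelial 0.945). A list used as its own covariate (acinar, pan-leukocyte) is not tested by that fit.

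Leaving out each library gave ranges across the threshold, or a turned sign, for neutrophil cytokine (0.000268 to 0.0941), other chemokine (0.013 to 0.509), MHC class I (0.00252 to 0.46), PI3K-AKT (0.222 to 0.83), RAS-ERK (0.00393 to 0.118), mesenchymal (0.0186 to 0.427), basal-like (0.0265 to 0.118), acinar (2.6e-08 to 0.944), duct (0.00595 to 0.0591) and DNA repair lists (0.214 to 0.837). The same held for S phase (2.79e-05 to 0.0587), G2 and M phase (4.43e-07 to 0.0588), TGF-beta and BMP (0.365 to 0.968), respiratory chain (0.000202 to 0.0523), cholesterol (0.000118 to 0.125), stress response (0.00727 to 0.364), matrix (0.00247 to 0.427) and checkpoint ligand lists (0.302 to 0.912). It held too for immediate early (0.547 to 0.98), ribosomal (0.00485 to 0.828), neutrophil (0.00185 to 0.223), fibroblast (0.249 to 0.955), endothelial (0.213 to 0.98), islet (0.00149 to 0.955) and mesothelial lists (0.135 to 0.82).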

Other observations

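Chosen after the result was seen were the acinar and leukocyte tests of the chromosome medians, the difference between lymphocyte and macrophage medians, the pan-leukocyte median with the acinar covariate, the values in libraries with at most 5% acinar reads, and the use of the epithelial median and of Xist to weigh the Y-linked genes. So were the comparisons of acinar read shares with chromosome medians and called genes, and the use of epithelial read shares. For the 2 covariate tests of chromosome medians, a bound on the spread was added after their first values were seen, and chromosomes 1, 3, 5 and 18 were picked from these data. Bootstrap intervals here were drawn over genes, which are not independent replicates. After first values were seen, the acinar dilution test was moved from KPSC replicate 3 alone to the whole list, since 1 library excludes nothing, which left its outcome as it was. The Xist limit was likewise widened, because the share of tumour RNA is not known, and this turned its outcome from excluded to open.

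Expressed genes along most of chromosomes 1, 3, 5 and 18 moved together between the groups. Relative to all expressed genes, the median log2 fold change was 0.371 on chromosome 1 (723 genes), -0.255 on chromosome 3 (616 genes), -0.253 on chromosome 5 (784 genes) and -0.381 on chromosome 18 (307 genes). On each of these, the medians of the 3 KPSC libraries lay apart from those of the 3 KPC libraries (exact permutation p = 0.1, the smallest possible); for chromosome 18 they were -0.375, -0.424 and -0.338 in KPSC against 0.041, 0.019 and -0.069 in KPC. Parts of these chromosomes did not lie beyond random draws of 40 genes (-0.21 to 0.225, all but the most extreme 0.1%), such as 171418872 to 175692901 on chromosome 1 (0.003) and 108970997 to 122619715 on chromosome 3 (-0.084). The distal part of chromosome 19 moved too, with a median of 0.61 over 40 genes from 47178820 to 58715770 (GRCm38), as did part of chromosome 2, with 0.488 over 40 genes from 62664285 to 73529734. Distal chromosome 2 moved the other way, with -0.345 over 40 genes from 164822686 to 168601657 (1 higher, 13 lower), so that its median over all genes hides 2 opposite shifts. Smaller shifts, beyond 95% of random draws of as many genes and with the groups apart, lay on chromosomes 14 (0.139), 19 (0.117), 16 (0.115), 2 (0.05) and 8 (-0.035). Chromosomes 4, 7, 9, 10 and 17 had medians within 0.013 of all genes. Across genes, fold change and gene length had a Spearman rho of -0.049 over 12190 genes, which are not independent replicates.

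The shifted chromosomes 1, 3, 5 and 18 held 19.9% of the genes tested and 770 of the 2406 called genes, 678 of them in the direction of their chromosome (28.2% of all calls). With the acinar level as a covariate, the smallest of the 4 medians was -0.246 (95% bootstrap interval -0.269 to -0.217), on chromosome 3. With the leukocyte level it was -0.214 (-0.256 to -0.171), also on chromosome 3. The shifts thus outlasted each adjustment, but neither fit by itself excludes unequal acinar or leukocyte RNA as their source. The acinar level correlated at only 0.21 with the group, so it could change group differences little. Library by library, acinar genes held 18.3%, 9.43% and 0.39% of reads in KPSC replicates 1, 2 and 3. In KPC replicates 1, 2 and 3 they held 2.46%, 0.941% and 7.22%. The chromosome 1 medians in the same order were 0.364, 0.355 and 0.392, and 0.019, 0.002 and -0.021. On all 4 chromosomes the medians followed the group and not the acinar share, which argues against acinar RNA as their source. The leukocyte level, at -0.9, can hardly be separated from the group. A candidate explanation is a difference in chromosome copy number between the tumour cells of the groups, which the median of -0.381 on chromosome 18 goes with; DNA was not analysed here, the design gives no group by which to separate this from genotype, and it covers only part of the calls. For the calls as a whole, the acinar covariate left the called fold changes at a median ratio of 1.004 to those without it. That ratio could hardly have moved, because the acinar level barely followed the group (0.21) and calls favour genes with little spread within groups. By itself that ratio does not exclude unequal carry-over of acinar cells. However, the groups did not overlap for any of the 2406 called genes. The acinar shares of the KPSC libraries, in contrast, lay both above and below those of every KPC library. This argues against acinar carry-over alone as the source of the calls. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 2406, and the highest other split gave 0 (limma); so few splits cannot give a share under 0.05.

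Camera called 5 lists of leukocyte markers lower in KPSC, 0 of them with an estimated correlation, and most markers did not pass, although the labels describe sorted tumour cells. The lymphocyte median lay below the macrophage median on the log2 scale (difference -0.76, 95% bootstrap interval -1.23 to -0.58), the lists sharing no gene. In the 3 libraries with at most 5% acinar reads, however, the medians were -0.47 and -0.45. A single smaller share of leukocytes of every kind forbids such a difference only if leukocytes alone supply both lists. That was not tested, so this explanation stays open. Dilution by acinar RNA is argued against only weakly, by a pan-leukocyte median of -0.41 (95% bootstrap interval -0.72 to -0.29) with the acinar covariate. The acinar level correlated at only 0.21 with the group, so that fit could change group differences little. Whether the sort differed between libraries or the tumours held different leukocytes stays open and untested.

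The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in all 3 KPSC libraries, Ddx3y at 19.3, 21.2 and 26.8 normalised reads against 659, 498 and 454. A smaller share of tumour cells in KPSC is argued against by the epithelial list, which did not fall with the Y-linked genes. Its median was 0.54 (95% bootstrap interval 0.28 to 0.90). The median was 0.30 without KPSC replicate 1, 1.02 without KPSC replicate 3 and 0.21 in the libraries with at most 5% acinar reads. The list took 0.746%, 0.838% and 0.926% of reads in KPSC replicates 1, 2 and 3, against 0.505%, 0.589% and 0.499% in KPC. Its mean log2 level in KPSC replicate 3, lowest in acinar reads, was 9.11, within the KPC range of 9.06 to 9.43. Acinar cells express some of its genes. The argument takes tumour cells of both groups to express the list alike, which was not tested. Tumour cells with an inactive X in KPSC in place of male cells may account for the pattern, but Xist, with a log2 fold change of -0.24 (95% interval -0.57 to 0.08), leaves this open, because other cells in the libraries can supply Xist. Loss of the Y chromosome and a different sex of the cells of origin cannot be told apart from these values, and a link to genotype is untested. Both readings take the Y-linked RNA to come from tumour cells, which was not tested, and other cells in the libraries may have supplied it.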
